A study of Mus musculus with 31 samples.

How the data were processed

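The series holds 31 RNA-seq libraries of C57BL/6 mice, 12 of bone-marrow-derived dendritic cells and 19 of spleens. Per the labels' protocols, marrow of male mice aged 8 to 16 weeks was cultured for 10 days with medium from a cell line that secretes GM-CSF, and LPS was given on day 11 for 8 h. The spleens came from mice aged 12 weeks, per the labels, and RNA was total RNA extracted with TRI reagent. Groups and replicate numbers were taken from the labels alone: naive wild-type, naive knockout, LPS wild-type and LPS knockout dendritic cells (n = 3 each), wild-type spleens (n = 10) and knockout spleens (n = 9).

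The deposited values are whole-number read counts per Ensembl gene, 1 file per library, with no normalization. TopHat 1.3.3, Bowtie, SAMtools, bedtools, DESeq and the mouse build mm9 are named, per the submitters' processing notes, without their roles. The annotation release, the use of strand and the treatment of reads with several places are not given in the sources used here, so overlapping genes, pseudogenes and gene families are uncertain. A share of 57.8 to 59.0% of the counts up to 200 was even in dendritic cells and 59.0 to 62.1% in spleens, as when both mates of a read pair are counted, so the counts are not all independent molecules. A gene with no line in a library's file was set to 0. Of 29120 gene IDs 26090 were named from a table of gene names. Gene places are those of GRCm38 (GENCODE M21 annotation) found by Ensembl ID, not of mm9.

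Total counts were 38998746 to 74164853 in dendritic cells and 56834377 to 133277070 in spleens. The 10 most abundant genes took 7.66 to 10.0% of them in dendritic cells and 6.98 to 26.1% in spleens. No libraries of a group agreed within sampling noise: the smallest chi-square per gene between libraries of a group was 26.6. A level of 0 was set against a floor of 3 counts over the group, which covers counting error only. Since the counts are not all independent molecules, that floor may be too low, and folds given as at least a value may be too large.

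The main test was edgeR's quasi-likelihood F-test (edgeR 4.0.16 in R 4.3.3) after edgeR's filter on low counts and TMM normalization, with robust dispersions and Benjamini-Hochberg adjustment at 0.05. The 12 dendritic cell libraries entered 1 fit with a mean per group (16965 genes, 8 residual degrees of freedom, biological coefficient of variation 0.311), and the 19 spleens another (20371 genes, 17 residual degrees of freedom, 0.394). The comparisons were LPS against naive in each genotype, knockout against wild-type in naive cells, LPS-treated cells and spleens, and the interaction of genotype and LPS. The SE of a log2 fold change is its size divided by the square root of F. CPM means and SDs use TMM-scaled library sizes unless the plain library size is named.

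Gene lists of pathways, signs of RNA quality and cell type markers were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the lists of a comparison. There were 34 lists with 639 members, of which 630 had an ID here. Sets with fewer than 4 tested members were not tested. Beside the calls stands camera's adjusted p under an estimated correlation, and fry was an alternative.

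The design, the lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule takes Gpr34 and called genes of the targeted region, then per comparison the 10 largest positive and 10 largest negative log2 fold changes among genes with an adjusted p under 0.05, a mean of at least 1 CPM in the higher group and, in dendritic cells, groups that do not overlap. Clone and predicted names are left out, and receptor segment families give at most 2 genes. Up to 4 members with the smallest p are named per described list, and the text names fewer in that order. The result of 1 single gene is not reported here. Genes named outside the rule are said to be chosen after their values were seen.

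Alternatives were DESeq2 1.42.0, limma voom with sample weights, RLE factors, no composition factors, no filter, only the libraries compared, a block on replicate number, 2 surrogate variables (sva 3.50.0) in spleen, and leaving out each library. Added after the data were seen were the removal of each library's trend with GC content and transcript length (lowess, span 0.3), the omission of 3 dendritic cell libraries labelled knockout that hold over 100 Gpr34 counts, the omission of knockout spleens 4, 6 and 9, and the omission of haemoglobin genes. GC content and length were known for 92.4% of the tested spleen genes. The tests were tested on simulated counts with 200 changed genes, 100 per fold size, and called no gene in the wrong direction. The changed genes had a mean of at least 1 CPM and the counts held no outlying library or GC trend, so the shares found hold for such data only. With a GC trend simulated in the knockout spleens (Spearman's rho of fold and GC content 0.634, against 0.359 in the real data) the spleen test made 624 false calls. It made 4 with the trend removed. Other splits of the samples were counted up to 100 per comparison. Tables and figures were made with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.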

Results

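RNA was sequenced from spleens and from dendritic cells of wild-type C57BL/6 mice and mice lacking Gpr34, a G protein-coupled receptor that responds to lysophosphatidylserine. The title of the series asks how Gpr34 expression is regulated. The dendritic cells, immune cells that present antigen to T cells, were grown from bone marrow with GM-CSF for 10 days, and a part of the cultures then received LPS, a bacterial cell wall component, for 8 h. The 31 libraries fell into 6 groups: 3 naive and 3 LPS-treated cultures labelled wild-type, 3 naive and 3 LPS-treated cultures labelled knockout, 10 wild-type spleens and 9 knockout spleens. Total counts per library ranged from 53585638 to 62282841 in naive wild-type and from 41801772 to 74164853 in naive cells labelled knockout. After LPS they ranged from 38998746 to 50809304 in wild-type and from 44460067 to 54513205 in cells labelled knockout. Spleens held 56834377 to 119384704 counts in wild-type and 80590338 to 133277070 in knockout. The labels number the replicates of a group without naming the animal behind each, so the p-values measure the spread between these libraries only, which may in part be technical.

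Gpr34 (ENSMUSG00000040229, chromosome X from 13632089 to 13640858, plus strand, GRCm38) was reported in each library, since it checks the labels. In spleen it was lower in the knockout, with 308 to 986 counts in the 10 wild-type and 42 to 156 counts in the 9 knockout libraries. The mean fell from 5.98 ± 1.55 CPM (SD, n = 10) to 1.05 ± 0.477 CPM (SD, n = 9), a log2 fold change of -2.51 (SE 0.25, adjusted p = 3.99e-05). Gpr82, the receptor gene next to Gpr34 (ENSMUSG00000047678, chromosome X from 13661363 to 13667433, plus strand), went the other way in spleen, from 0.282 ± 0.161 CPM (SD, n = 10) to 2.95 ± 0.963 CPM (SD, n = 9), with a log2 fold change of 3.38 (SE 0.33, adjusted p = 3.99e-05). Both genes lie within Cask, which runs on the minus strand from 13517080 to 13851367, and the sources used here do not state whether the counting used strand, so reads of Cask could not be separated from theirs. Cask had a log2 fold change of -0.35 (SE 0.11) that did not pass over all genes (adjusted p = 0.138). Among the 19 genes fixed for the targeted region, 5 of those tested passed when adjusted over the list alone: Gpr82, Gpr34, Mid1ip1 at 0.45, Cask and Nyx at -0.71.

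The dendritic cells labelled knockout did not all follow their label. Gpr34 had 324, 199 and 226 counts in naive wild-type replicates 1, 2 and 4 and 125, 65 and 65 counts in LPS-treated wild-type replicates 1, 2 and 3. It had 0, 120 and 4 counts in naive replicates 2, 3 and 4 labelled knockout, and 0, 117 and 104 counts in LPS-treated replicates 2, 3 and 4 labelled knockout. Thus 3 of the 6 libraries labelled knockout held over 100 counts, so the 6 are called libraries labelled knockout throughout. Where libraries labelled knockout with Gpr34 reads are named below, these 3 are meant. Mean Gpr34 was 3.75 ± 0.927 CPM in naive wild-type, 0.520 ± 0.830 CPM in naive cells labelled knockout, 2.29 ± 1.03 CPM in LPS-treated wild-type and 1.52 ± 1.32 CPM in LPS-treated cells labelled knockout (SD, n = 3 each). The genotype difference did not pass in naive cells (log2 fold change -2.79, SE 1.38, adjusted p = 0.765) or after LPS (-0.58, SE 1.3, adjusted p = 0.910). The LPS effect on Gpr34 in wild-type cells did not pass either (-0.71, SE 1.29, adjusted p = 0.719), in a fit of 12 libraries whose spread for this gene takes in the libraries labelled knockout. Fitted on the 6 wild-type libraries alone it was -0.74 (adjusted p = 0.152). In CPM of the plain library size, Gpr34 was at 3.63 to 5.59 in naive and 1.28 to 2.97 in LPS-treated wild-type libraries. These ranges did not overlap. With TMM-scaled library sizes they did, at 3.17 to 4.82 CPM and 1.46 to 3.44 CPM. Whether the groups overlapped thus depended on the scaling, and no test of Gpr34 without composition factors is given here. In dendritic cells Gpr82 stayed near 1 CPM, with a genotype log2 fold change of 0.06 (SE 0.91) in naive cells and -0.45 (SE 0.92) after LPS, and LPS-treated replicate 2 labelled knockout had 0 counts of it. Levels are not compared between the tissues, because housekeeping genes differed by far between them: Gapdh was at 3.02 to 7.23 CPM in the dendritic cell groups and at 93.7 and 109 CPM in the spleen groups.

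**Figure D1:**
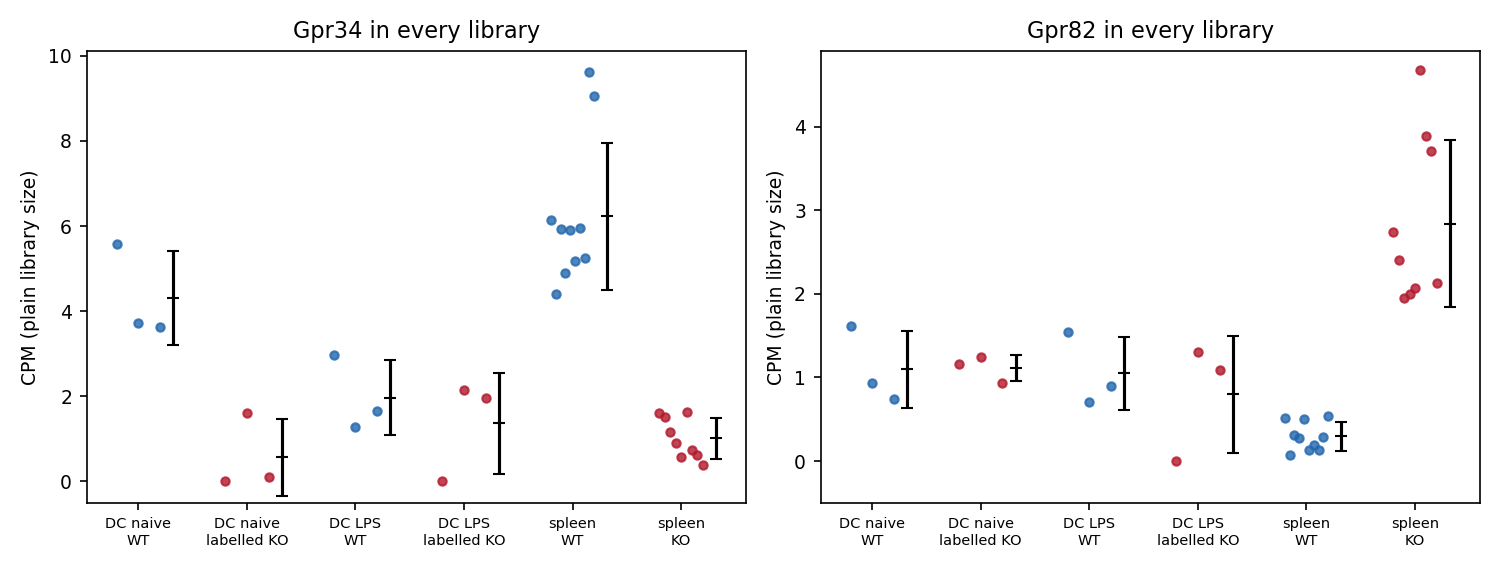
Gpr34 and Gpr82 in CPM of the plain library size (vertical axes) for each library (points) of the 6 groups (horizontal axis), with the group mean and SD as bars. In spleen, Gpr34 lies lower and Gpr82 higher in all 9 knockout libraries than in all 10 wild-type libraries. Of the 6 dendritic cell libraries labelled knockout, 3 lie at 1.62 to 2.15 CPM of Gpr34. Of these 3, naive replicate 3 is at 1.62 CPM (naive wild-type 3.63 to 5.59 CPM). LPS-treated replicates 3 and 4 are at 2.15 and 1.96 CPM (LPS-treated wild-type 1.28 to 2.97 CPM). Naive replicate 4 labelled knockout held 4 counts of Gpr34, and replicate 2 labelled knockout of each treatment held 0.

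LPS treatment of wild-type dendritic cells raised genes of inflammation and of the interferon response and lowered genes of cell division. Csf3, the granulocyte growth factor, went from 0 counts in the 3 naive libraries to 14.4 ± 2.81 CPM (SD, n = 3), at least 949.7-fold higher against a floor of 3 counts over the group. Saa1, an acute phase protein, went from 0 counts to 9.28 ± 1.26 CPM, at least 609.6-fold higher. Il12a, a subunit of interleukin 12, rose from 0.0286 ± 0.0281 to 22.6 ± 1.20 CPM, the glutamate transporter gene Slc1a2 from 0.431 ± 0.323 to 252 ± 128 CPM, and the non-coding transcript U90926 from 0.0407 ± 0.0451 to 27.5 ± 8.57 CPM. Gstm6 and Kcnn1 were also at 0 counts without LPS and were at least 229.2-fold and 130.7-fold higher with it. Cyp4f15, a cytochrome P450, fell from 11.9 ± 1.53 CPM to 0 counts, at least 452.4-fold lower. Nxpe5 fell from 5.44 ± 0.480 CPM to 0 counts, at least 207.6-fold lower, and Htra3 from 2.98 ± 1.59 CPM to 0 counts, at least 113.5-fold lower.

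All 27 tested genes of the list of NF-kB targets and inflammatory cytokines were higher with LPS, with a median log2 fold change of 6.02 (camera adjusted p = 2.4e-25, adjusted p = 0.133 with an estimated correlation). Ptgs2, which makes prostaglandins, rose from 1.3 ± 0.237 to 439 ± 83.2 CPM (log2 fold change 8.40, SE 0.22), Lcn2 by a log2 fold change of 6.06 (SE 0.22), and the cytokine genes Il6 and Il12b by 7.12 (SE 0.39) and 7.09 (SE 0.39). All 25 interferon-stimulated genes were higher, with a median of 2.76 (camera adjusted p = 3.07e-25, adjusted p = 0.133 with an estimated correlation). They included the chemokine gene Cxcl10 at 6.93 (SE 0.25), Usp18 at 3.12 (SE 0.13), Gbp2 at 2.76 (SE 0.12) and Stat2 at 1.80 (SE 0.08). Of 20 dendritic cell maturation genes 17 were higher and 3 did not pass (median 1.5, camera adjusted p = 1.83e-08, adjusted p = 0.520 with an estimated correlation). Examples were Cd274, which encodes PD-L1, at 1.77 (SE 0.18), the chemokine gene Ccl17 at 2.95 (SE 0.31) and Traf1 at 1.56 (SE 0.16). Of 24 cell cycle genes 20 were lower, 1 was higher and 3 did not pass (median -2.35, camera adjusted p = 6.93e-07, adjusted p = 0.601 with an estimated correlation). The mitotic genes Bub1b, Cdc20 and Aurkb had log2 fold changes of -2.64 (SE 0.42), -3.23 (SE 0.52) and -2.96 (SE 0.49), while Tyms, which makes thymidylate, was the higher gene at 1.42 (SE 0.10). Of 22 glycolysis and hypoxia genes 15 were higher (camera adjusted p = 2.75e-04, adjusted p = 0.520 with an estimated correlation). Examples were the hexokinase 2 gene Hk2 at 2.15 (SE 0.16) and Pfkp at 1.06 (SE 0.09).

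Smaller groups moved as well. Of 27 genes of integrins, cytoskeleton and motility 14 were higher and 4 lower (camera adjusted p = 0.0328, adjusted p = 0.520 with an estimated correlation). Itgal, Itga5 and Vasp rose by log2 fold changes of 1.79 (SE 0.11), 2.15 (SE 0.16) and 0.77 (SE 0.08). The chemokine receptor genes Ccr2 and Cxcr4 fell by 5.62 (SE 0.53) and 2.18 (SE 0.23). Of 17 endoplasmic reticulum stress genes 10 were higher and 3 lower (camera adjusted p = 0.0396, adjusted p = 0.718 with an estimated correlation). Examples were Atf4 at 0.70 and Asns at 1.55. Of 9 markers of red pulp and marginal zone macrophages 4 were higher, led by Marco at 3.75 and Vcam1 at 3.91 (camera adjusted p = 0.0489, adjusted p = 0.353 with an estimated correlation). Of 12 heat shock genes 6 were higher (camera adjusted p = 0.0489, adjusted p = 0.601 with an estimated correlation), though their median went from 0.39 to -0.01 without composition factors. Of 24 ribosomal protein genes, a sign of RNA quality, 5 were lower (camera adjusted p = 0.0489, adjusted p = 0.737 with an estimated correlation). The list of lysophospholipid receptors and enzymes, to which Gpr34 belongs, did not pass as a set (camera adjusted p = 0.384), but 3 of its 14 genes were higher and 6 lower. Pla1a, which makes lysophosphatidylserine, was at 3.95 (SE 0.43) and Lpar6 at -1.85 (SE 0.26).

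By edgeR's quasi-likelihood test 3064 genes were higher and 2679 lower with LPS in wild-type cells out of 16965 tested, and 1421 and 1449 of these changed at least 2-fold. Without naive replicate 3 labelled knockout, which shares the fit, the NF-kB and maturation lists passed with an estimated correlation too (adjusted p = 0.0240 with an estimated correlation for each). The groups did not overlap for 50.9% of the genes, where chance gives 10% for 3 against 3. Without composition factors the median over all genes was -0.44 and the counts were 1599 higher and 6128 lower, so the split between higher and lower depended on the scaling. Integrin and motility genes were then 9 higher and 9 lower (median 0.06 against 0.47), endoplasmic reticulum stress genes 4 and 4 (0.06 against 0.47), and glycolysis genes 4 and 2 (0.19 against 0.60). Ribosomal protein genes were 0 and 20, maturation genes 14 and 1, red pulp and marginal zone macrophage markers 3 and 1, NF-kB genes 26 and 0, interferon genes 25 and 0, and cell cycle genes 1 and 23. General macrophage markers, which did not pass as a list (camera adjusted p = 0.290), were 1 higher and 9 lower against 2 and 3 with the factors. The integrin, endoplasmic reticulum stress and heat shock calls were lost without the factors (camera adjusted p = 0.0609, 0.0523 and 0.194). The NF-kB and interferon lists then passed with an estimated correlation (adjusted p = 0.0331 and 0.0275 with an estimated correlation).

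In the cells labelled knockout LPS gave a response led by many of these genes. Csf3 went from 3 counts over the 3 naive libraries (0.0158 ± 0.0178 CPM) to 22.3 ± 8.33 CPM (SD, n = 3). Saa1 went from 0 counts to 5.67 ± 2.60 CPM, at least 342.3-fold higher. Gstm6 went from 0 counts to 5.40 ± 2.54 CPM, at least 325-fold higher. Ms4a4d went from 0 counts to 7.62 ± 3.35 CPM, at least 466.5-fold higher, and Sytl3 was at least 144.7-fold higher. U90926 rose from 0.0246 ± 0.0426 to 25.9 ± 12.4 CPM and Ptgs2 from 1.86 ± 0.214 to 537 ± 66.2 CPM (log2 fold change 8.17, SE 0.21). Robo4, a receptor of endothelial cells, fell from 4.93 ± 2.21 CPM to 0 counts, at least 215.4-fold lower. Lpar5, a receptor for lysophosphatidic acid, fell from 2.50 ± 1.09 CPM to 0 counts, at least 104.7-fold lower, and Slco2b1, a transporter of organic anions, was at least 92.26-fold lower. Pdgfrb rose from 0.925 ± 0.143 to 177 ± 294 CPM, a mean set by replicate 2, which held 458.1 CPM of the plain library size.

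All 27 NF-kB and cytokine genes were higher (median 5.23, camera adjusted p = 3.2e-27, adjusted p = 0.114 with an estimated correlation). Examples were Lcn2 at 5.64 (SE 0.21), Il27 at 4.93 (SE 0.28), Il1a at 6.23 (SE 0.37) and Il6 at 6.01 (SE 0.37). All 25 interferon-stimulated genes were higher (median 2.94, camera adjusted p = 2.71e-28, adjusted p = 0.0942 with an estimated correlation). Examples were Cxcl10 at 6.15 (SE 0.24), Usp18 at 2.98 (SE 0.12), Stat2 at 1.84 (SE 0.08) and Oas3 at 2.94 (SE 0.13). Of 20 maturation genes 17 were higher (median 1.24, camera adjusted p = 1.9e-08, adjusted p = 0.522 with an estimated correlation). Examples were Il12b at 6.01 (SE 0.37), Cd274 at 1.71 (SE 0.18) and Traf1 at 1.27 (SE 0.16). Of 24 cell cycle genes 20 were lower and 1, again Tyms, was higher (median -2.13, camera adjusted p = 1.12e-05, adjusted p = 0.716 with an estimated correlation). Examples were Plk1 at -2.93 (SE 0.52), Aurkb at -2.65 (SE 0.49) and Bub1b at -2.11 (SE 0.41). Of 22 glycolysis and hypoxia genes 11 were higher (camera adjusted p = 6.73e-04, adjusted p = 0.522 with an estimated correlation), led by Hk2 at 2.10 (SE 0.16) and Pfkp at 0.90 (SE 0.09). Of 9 red pulp and marginal zone macrophage markers 5 were higher and 1 lower (camera adjusted p = 0.00893, adjusted p = 0.120 with an estimated correlation). Of 26 MAPK and immediate early genes 12 were higher and 2 lower (camera adjusted p = 0.00958, adjusted p = 0.297 with an estimated correlation). Examples were Ier3 at 1.96 (SE 0.14) and Atf3 at 2.11 (SE 0.20). The median of that list went from 0.27 to -0.07 without composition factors. Of 24 ribosomal protein genes 5 were lower (camera adjusted p = 0.0128, adjusted p = 0.722 with an estimated correlation). Of the 14 lysophospholipid genes 2 were higher and 4 lower (camera adjusted p = 0.411).

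**Figure D2:**
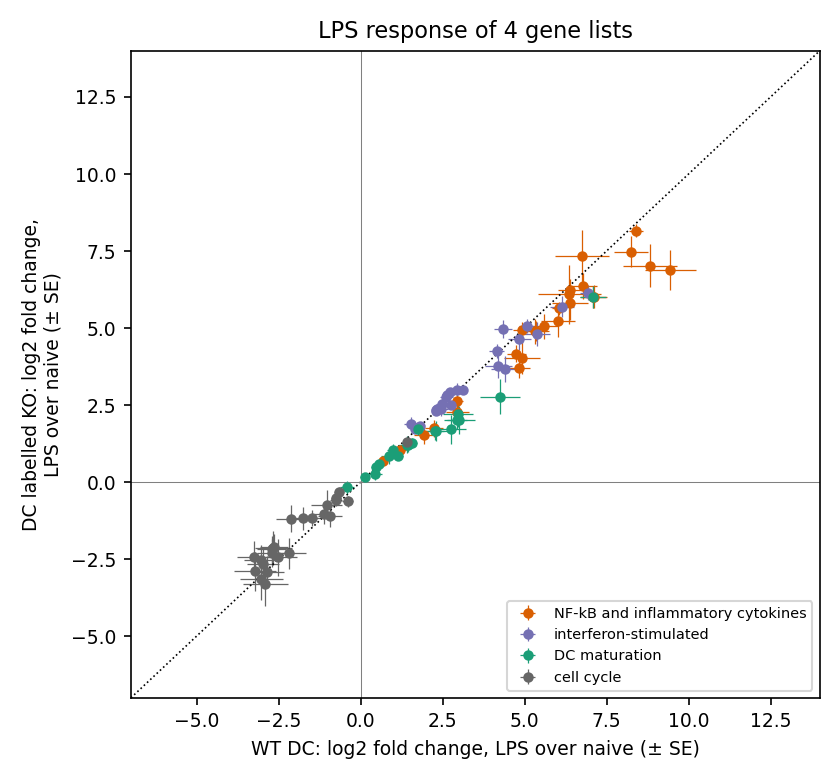
LPS response of single genes of 4 lists, as log2 fold change in wild-type cells (horizontal axis) against cells labelled knockout (vertical axis), with SE as bars, 3 libraries per group; Csf3 and Ifnb1, which had 3 counts or fewer in a naive group, are not drawn. NF-kB and interferon genes lie above 0 in both, and all cell cycle genes but Tyms lie below 0.

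The test called 2601 genes higher and 2274 lower in cells labelled knockout, with 1139 and 1172 changed at least 2-fold and 41.7% of genes with groups that did not overlap. These counts depended on single libraries. Leaving out naive replicate 3 labelled knockout gave 2936 and 2672, and 3037 and 3068 in wild-type cells in that fit. Leaving out naive replicate 2 or 4 labelled knockout gave 1986 and 1585, and 1865 and 1570. Without naive replicate 3 labelled knockout the NF-kB and maturation lists passed with an estimated correlation (adjusted p = 0.0194 with an estimated correlation for each). Without composition factors the counts were 1441 higher and 4986 lower, with a median over all genes of -0.35. Glycolysis genes were then 5 higher and 2 lower (median 0.10 against 0.43), ribosomal protein genes 0 and 20, maturation genes 14 and 0, and NF-kB and interferon genes 27 and 25 higher. The NF-kB, interferon and red pulp macrophage lists then passed with an estimated correlation (adjusted p = 0.0331, 0.0224 and 0.0331 with an estimated correlation). Of the called genes 2309 were higher and 1770 lower in both responses, where independent lists would share 470 and 359, and 1 gene was called in opposite directions. The 2 responses have no library in common, but both come from 1 fit that shares the estimated spread of each gene, so independence is not assured.

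Whether the LPS response differed with the label was tested by the interaction of genotype and LPS. No gene passed in edgeR's quasi-likelihood test, with 678 genes at an unadjusted p under 0.05 where 848 are expected by chance. On the same contrast DESeq2 called 11 higher and 11 lower and limma voom called 0. The test found 73% of the genes given a 4-fold interaction in simulated data and 17% of those given a 2-fold interaction. Among the lists, 26 of the 27 NF-kB and cytokine genes had a negative value, that is a smaller rise in the cells labelled knockout (median -0.49, camera adjusted p = 0.00285, adjusted p = 0.814 with an estimated correlation). Examples were Il6 at -1.10 (SE 0.43), Il12b at -1.08 (SE 0.42) and Ccl4 at -1.11 (SE 0.43). The cholesterol synthesis list was lower in all 18 genes (median -0.38, camera adjusted p = 0.00782, adjusted p = 0.814 with an estimated correlation). Of 13 genes of MHC class II presentation 12 were negative (camera adjusted p = 0.00782, adjusted p = 0.814 with an estimated correlation). H2-Ab1 among them was at -0.53 (SE 0.25). Cell cycle genes were positive in 17 of 24 (camera adjusted p = 0.0436, adjusted p = 0.814 with an estimated correlation). Without naive replicate 3 labelled knockout, the NF-kB and cell cycle calls were lost (camera adjusted p = 0.574 and 0.455). The MHC class II and cholesterol calls were then kept (0.0491 and 4.67e-08), and MAPK genes passed as higher and general macrophage markers as lower (0.0491 each). With an estimated correlation none of these lists passed in that fit, with adjusted p = 0.521 for MAPK and 0.767 for cholesterol, MHC class II and macrophage markers with an estimated correlation. Without the 3 libraries labelled knockout that held Gpr34 reads, the cholesterol list (camera adjusted p = 0.0488) and a lower glycolysis list (0.00957) passed, each with adjusted p = 0.977 with an estimated correlation. That fit leaves replicate 2 alone after LPS and assumes that it varies like the other groups. The cell cycle call was lost without composition factors (camera adjusted p = 0.0911) and with the GC and length trend of each library removed (0.0507).

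In naive dendritic cells no gene passed between the labels, so what follows are levels and list tests. Pls3, an actin-bundling protein gene on chromosome X, had the smallest adjusted p, 0.0837: it was at 120 ± 17.4 CPM in wild-type and 38.2 ± 11.0 CPM in the cells labelled knockout (SD, n = 3 each), a log2 fold change of -1.65 (SE 0.20). It is named here because it was the closest to passing, after its values were seen. Endoplasmic reticulum stress genes were positive in 16 of 17 (median 0.24, camera adjusted p = 5.64e-05, adjusted p = 0.594 with an estimated correlation). Adjusted over the list alone 2 passed, Asns at 0.84 (SE 0.23) and Hsp90b1 at 0.39 (SE 0.11). Cell cycle genes were negative in 22 of 24 (median -0.35, camera adjusted p = 5.64e-05, adjusted p = 0.771 with an estimated correlation). Examples were Mcm6 at -0.36 (SE 0.15), Mcm5 at -0.38 (SE 0.19) and Cdc20 at -0.81 (SE 0.47), none of them passing over the list alone. NF-kB and cytokine genes were positive in 22 of 27 (median 0.35, camera adjusted p = 0.0211, adjusted p = 0.771 with an estimated correlation). Examples were Il12b at 0.96 (SE 0.30) and Il6 at 0.94 (SE 0.32).

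Lists with lower values in the naive cells labelled knockout were interferon-stimulated genes (camera adjusted p = 0.0276, adjusted p = 0.771 with an estimated correlation), of which Igtp passed over the list alone at -0.45 (SE 0.11). MAPK and immediate early genes were lower as well (camera adjusted p = 0.0276, adjusted p = 0.567 with an estimated correlation). Adjusted over that list alone, 1 gene was higher and 4 lower. These were Ier2, Fos, Dusp6 and Egr1 at -0.82 (SE 0.17), -2.29 (SE 0.59), -1.03 (SE 0.30) and -2.27 (SE 0.71), and Atf3 at 0.66 (SE 0.20). Markers of mast cells, basophils and eosinophils (2 of 11 positive, camera adjusted p = 0.0335, adjusted p = 0.594 with an estimated correlation) and ribosomal protein genes (4 of 24 positive, camera adjusted p = 0.0362, adjusted p = 0.771 with an estimated correlation) were lower too. Naive replicate 3 labelled knockout stood apart from the other naive libraries, at 31.4% of the way to the LPS-treated libraries on the leading principal component, where the others lay between -2.6 and 3.22%. Without it the NF-kB, cell cycle, mast cell and ribosomal calls were lost (camera adjusted p = 0.465, 0.863, 0.275 and 0.542). The endoplasmic reticulum stress, MAPK and interferon calls were kept (0.00437, 0.00145 and 4.16e-05). The maturation list, which did not pass with all libraries (median 0.27, camera adjusted p = 0.0943), was then lower with camera adjusted p = 0.00145 (adjusted p = 0.416 with an estimated correlation). The 3 calls kept had adjusted p = 0.805, 0.106 and 0.533 with an estimated correlation in that fit. The trend of a library with the GC content of the genes was taken on its difference from the mean of the 12 dendritic cell libraries, so its sign is relative to them. It was positive in 3 of 3 naive wild-type libraries (Spearman's rho 0.0682 to 0.139) and in 1 of 3 labelled knockout (-0.110 to 0.0575). With the trend in GC content and transcript length removed, the MAPK and ribosomal calls were lost (camera adjusted p = 0.120 and 0.401). MHC class II and maturation genes then passed as higher (camera adjusted p = 0.0128 and 0.0479, adjusted p = 0.759 and 0.772 with an estimated correlation).

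The test on single genes found 0 higher and 0 lower in edgeR's quasi-likelihood test with 1139 genes at an unadjusted p under 0.05 (848 expected). That number was 681 without naive wild-type replicate 2 and 1721 with limma voom, and the highest of 9 other splits of the 6 libraries gave 1114. By other tools, DESeq2 called 45 higher and 32 lower and limma voom 0 higher and 1 lower, Pls3. Groups did not overlap for 13.1% of the genes. In simulated data the test found 87% of genes changed 4-fold and 50% of those changed 2-fold. Without naive replicate 4 labelled knockout Pls3 passed (adjusted p = 0.0451), and without LPS-treated wild-type replicate 2 Rnmt passed at -0.85 (adjusted p = 0.0348).

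After LPS the cells labelled knockout had lower values than wild-type for all 18 tested genes of cholesterol synthesis (median -0.52, camera adjusted p = 5.93e-06, adjusted p = 0.861 with an estimated correlation). Mvk, Fdft1, Nsdhl and Sqle, which encode enzymes of that pathway, were at -0.46 (SE 0.18), -0.74 (SE 0.29), -0.53 (SE 0.21) and -0.71 (SE 0.31). Sqle was at 67.1 ± 6.45 CPM in wild-type and 40.9 ± 12.0 CPM in cells labelled knockout (SD, n = 3 each). Markers of mast cells, basophils and eosinophils were positive in 2 of 11 (median -0.94, camera adjusted p = 0.00563, adjusted p = 0.603 with an estimated correlation). The basophil protease gene Prss34, at -1.71 (SE 0.48), was the 1 gene passing over the list alone. Markers of stroma and endothelium (3 of 15 positive, camera adjusted p = 0.0300), interferon-stimulated genes (5 of 25 positive, camera adjusted p = 0.0340) and ribosomal protein genes (1 of 24 positive, camera adjusted p = 0.0340) were lower. Each of these had adjusted p = 0.861 with an estimated correlation. Endoplasmic reticulum stress genes were higher (15 of 17 positive, camera adjusted p = 0.0316, adjusted p = 0.861 with an estimated correlation). Members of these lists were Col6a1 at -2.48 (SE 0.83), Igtp at -0.42 (SE 0.10), Cxcl10 at -0.64 (SE 0.19), Rps9 at -0.18 (SE 0.08) and Dnajb9 at 1.03 (SE 0.35), and adjusted over the list alone 0 genes of these lists passed.

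No gene passed alone: edgeR's quasi-likelihood test gave 0 higher and 0 lower with 1914 genes at an unadjusted p under 0.05 (848 expected). Other tools gave more calls or none, DESeq2 224 higher and 148 lower, and limma voom 0. Groups did not overlap for 17.5% of the genes, and the test found 87% of genes changed 4-fold and 59% of those changed 2-fold in simulated data. Without the 3 libraries labelled knockout with Gpr34 reads, which leaves replicate 2 alone after LPS and assumes that it varies like the other groups, none of the 6 list calls was kept (cholesterol at camera adjusted p = 0.126). In that fit the glycolysis list was lower. Tcof1 and Pdgfrb had log2 fold changes of 4.01 and 6.25, and Depdc1b of -8.42. Tcof1, Camk2a, Pdgfrb, Arsi and Slc6a7, which were higher in that fit, lie in 1 run of neighbouring genes on chromosome 18. Among the dendritic cell libraries that run was high in LPS-treated replicate 2 labelled knockout alone. Their values thus rest on 1 library and are not read as an effect of the label. Relative to the mean of the 12 dendritic cell libraries, the trend with GC content was positive in 2 of 3 LPS-treated wild-type libraries (Spearman's rho -0.0426 to 0.0883) and in 0 of 3 labelled knockout (-0.116 to -0.102). With that trend and the one in length removed the cholesterol call was kept (camera adjusted p = 2.01e-06, adjusted p = 0.965 with an estimated correlation) and the ribosomal call was lost (0.702). Without composition factors the ribosomal and interferon calls were lost (0.116 and 0.0514). The genes named in this paragraph were chosen after their values were seen. Without naive replicate 3 labelled knockout Dst and Kpna4 were higher (adjusted p = 0.0482 each). Without naive replicate 2, LPS-treated replicate 2 or LPS-treated replicate 4 labelled knockout 1 gene was lower, Pls3 (0.0445), Chil6 (0.0111) and Ak1 (0.0383) in turn.

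In spleen 36 genes passed between knockout and wild-type by edgeR's quasi-likelihood test, where DESeq2 called 900 and limma voom 790. At least 2-fold were 1 gene higher, Gpr82, and 6 lower, Gpr34, Mapt and 4 IDs with no name in the table used, at -1.34 to -1.79. Tgfb1, which encodes the cytokine TGF-beta 1, rose from 81.5 ± 9.91 CPM (SD, n = 10) to 124 ± 17.5 CPM (SD, n = 9), a log2 fold change of 0.61 (SE 0.09, adjusted p = 0.00532). Srebf2, the transcription factor of cholesterol synthesis, rose from 131 ± 17.1 to 187 ± 24.9 CPM (0.51, SE 0.09, adjusted p = 0.0192). Idi1, an enzyme of that pathway, rose from 9.88 ± 1.3 to 14.3 ± 1.92 CPM (0.53, SE 0.09, adjusted p = 0.0215). Mapt, which encodes the protein tau, fell from 3.73 ± 1.71 to 1.10 ± 0.454 CPM (-1.76, SE 0.29, adjusted p = 0.0183). Pdgfra, a receptor of stromal cells, fell from 24.0 ± 4.63 to 13.5 ± 2.89 CPM (-0.82, SE 0.13, adjusted p = 0.0162), and Cp, which encodes ceruloplasmin, from 163 ± 21.1 to 111 ± 23.0 CPM (-0.56, SE 0.11, adjusted p = 0.0414). The lactate transporter gene Slc16a3, the splicing factor gene Sf3b4, the actin gene Actb and Arpc4, which encodes a subunit of the complex that starts actin filaments, were higher at 0.58 (SE 0.12), 0.48 (SE 0.09), 0.45 (SE 0.09) and 0.45 (SE 0.09). Abca8b, Rfx3, Fyco1, Zfc3h1, Masp2 and Fam214a were lower at -0.85 (SE 0.17), -0.79 (SE 0.15), -0.66 (SE 0.12), -0.56 (SE 0.11), -0.50 (SE 0.09) and -0.47 (SE 0.09). With each library's trend in GC content and transcript length removed, Rfx3 at -0.44 (adjusted p = 0.0801), Abca8b at -0.57 (0.178) and Slc16a3 at 0.50 (0.0611) no longer passed. The ferritin pseudogenes Ftl2-ps and Ftl1-ps1 were higher at 0.60 (SE 0.07) and 0.57 (SE 0.08), and are uncertain because they share reads with the ferritin light chain gene. Both were at 0.37 with that trend removed.

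**Figure D3:**
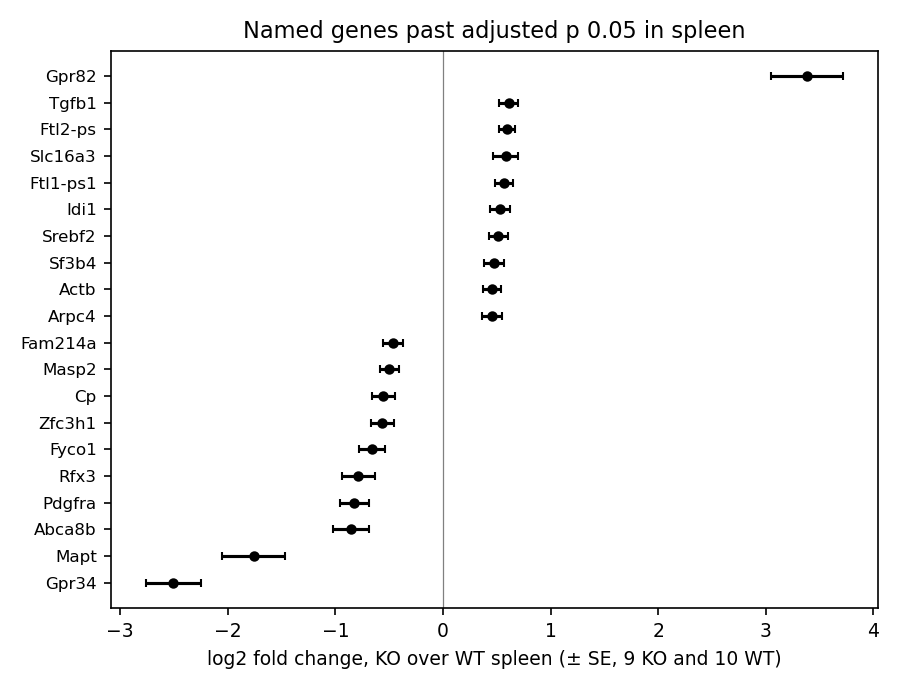
Log2 fold change of knockout against wild-type spleens (horizontal axis) for the 20 genes named by the fixed rule, with SE as bars, from 9 knockout and 10 wild-type libraries. Gpr82 and Gpr34 lie farthest from 0, at 3.38 and -2.51, and the other genes lie between -1.76 and 0.61.

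Cholesterol synthesis genes were positive in 16 of 18 in knockout spleens (median 0.24, camera adjusted p = 1.98e-07, adjusted p = 0.132 with an estimated correlation). Of these genes 2 passed over all genes and 9 when adjusted over the list alone, among them Srebf2, Idi1 and Fdps at 0.75 (SE 0.16). All 12 heat shock genes were positive (median 0.33, camera adjusted p = 3.37e-05, adjusted p = 0.638 with an estimated correlation). Hsp90ab1 at 0.42 (SE 0.10), Dnajb1 at 0.38 (SE 0.10) and Bag3 at 0.41 (SE 0.13) passed over the list alone. Plasma cell markers were negative in all 11 (median -0.27, camera adjusted p = 0.00199, adjusted p = 0.816 with an estimated correlation). Prdm1, Sdc1 and Jchain passed over the list alone at -0.53 (SE 0.17), -0.36 (SE 0.12) and -0.37 (SE 0.13). Interferon-stimulated genes were positive in 17 of 24 (camera adjusted p = 0.0348, adjusted p = 0.816 with an estimated correlation), and 5 passed over the list alone, led by Irf7 at 0.40 (SE 0.10). Cell cycle genes were positive in all 24 (camera adjusted p = 0.00199), with Plk1 at 0.60 (SE 0.19), as were the 24 ribosomal protein genes (camera adjusted p = 2e-04) and the 16 histone genes (camera adjusted p = 0.0299). Each of these lists had adjusted p = 0.816 with an estimated correlation. Genes of MAPK signalling and immediate early response (20 of 27 positive, camera adjusted p = 0.0299), glycolysis (15 of 22, camera adjusted p = 0.0358) and MHC class II presentation (11 of 13, camera adjusted p = 0.0358) were higher, and those of the PI3K, AKT and FOXO pathway were lower (6 of 24 positive, camera adjusted p = 0.0358). These lists also had adjusted p = 0.816 with an estimated correlation. Without composition factors cholesterol genes were positive in 12 of 18, with a median of 0.12 and 0 genes passing over all genes. The median was then 0.02 against 0.12 for interferon, 0.17 against 0.30 for cell cycle, 0.12 against 0.24 for ribosomal protein, 0.09 against 0.20 for MAPK and -0.23 against -0.11 for PI3K genes. The glycolysis (0.06 against 0.18) and MHC class II calls (0.08 against 0.19) were lost (camera adjusted p = 0.0619 and 0.144).

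Markers of other tissue and cell types moved beside these groups. Pancreas markers were positive in 21 of 22 (median 1.45, camera adjusted p = 0.00199, adjusted p = 0.816 with an estimated correlation), but none passed alone. The amylase gene Amy2a5 was at 289 ± 449 CPM in wild-type and 1473 ± 1885 CPM in knockout spleens, and the elastase gene Cela1 at 45.6 ± 56.7 and 150 ± 179 CPM. Erythroid markers were positive in all 25 without passing as a set (camera adjusted p = 0.390; 0.0213 without composition factors, adjusted p = 0.875 with an estimated correlation), and haemoglobin genes took 9.88% ± 5.94 of the counts in knockout and 7.63% ± 2.78 in wild-type spleens. Relative to the mean of the 19 spleens, a trend with the GC content of the genes was positive in 8 of 9 knockout and 3 of 10 wild-type spleens. With each library's trend in GC content and transcript length removed, cholesterol (camera adjusted p = 8.12e-09, adjusted p = 0.0838 with an estimated correlation), heat shock, plasma cell, interferon, cell cycle, ribosomal and pancreas calls were kept and the other 5 were lost. Without knockout replicates 4, 6 and 9, which were picked after the data were seen, the cell cycle (camera adjusted p = 0.263), pancreas (0.398), histone (0.400) and PI3K (0.244) calls were lost and the cholesterol call was kept (1.71e-09, adjusted p = 0.0245 with an estimated correlation). B cell and T cell markers did not pass (camera adjusted p = 0.230 and 0.390), and neither did the 15 lysophospholipid genes (0.172), where Gpr34 was the 1 gene that passed over all genes.

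**Figure D4:**
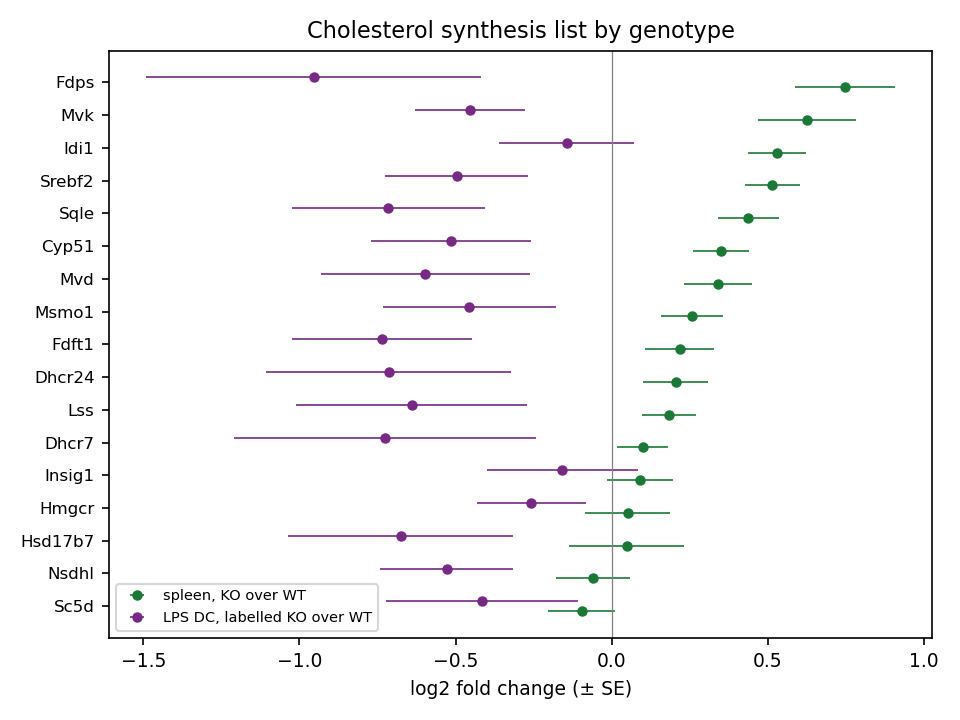
Log2 fold change with SE bars (horizontal axis) of 17 of the 18 tested cholesterol synthesis genes (vertical axis) for knockout against wild-type spleens (9 and 10 libraries) and for LPS-treated dendritic cells labelled knockout against wild-type (3 and 3 libraries). In spleen 15 of the 17 genes drawn lie above 0, and in the dendritic cells all 17 lie below 0.

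The spleen test called 20 genes higher and 16 lower of 20371 tested, and 7 higher and 183 lower without composition factors, where the median over all genes was -0.10, with 3541 at an unadjusted p under 0.05 (1019 expected), and in simulated data it found 84% of genes changed 2-fold. The count depended on the test, on a block and on single spleens. DESeq2 called 461 higher and 439 lower, limma voom 383 and 407, and a block on replicate number left 2 and 1. Same-numbered spleens correlated at a median of 0.143 against -0.0205 for other pairs, so whether the numbers pair the spleens stays open. Leaving out 1 of the 19 spleens at a time moved the total of 36 by over 1.5 times for 16 of them. Totals without knockout replicate 1, 2, 3, 4, 6, 7, 8 and 9 were 21, 23, 19, 22, 1051, 21, 8 and 23 in turn, and without wild-type replicate 1, 2, 3, 4, 5, 7, 9 and 10 they were 23, 103, 22, 55, 15, 18, 23 and 17 in turn.

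Across the comparisons the genotype effects were not shared by called genes, since 0 genes passed in dendritic cells. At an unadjusted p under 0.05, naive and LPS-treated cells labelled knockout shared 262 higher and 77 lower genes, where independent lists would share 48.6 and 18.9. Independence is not assured here, since the cultures labelled knockout carry the same replicate numbers in both treatments. The trend with GC content was also lower in the libraries labelled knockout in both, and this overlap was not counted with that trend removed. Between spleen and naive cells 14 higher and 37 lower genes were shared (72.1 and 33.6 expected), and between spleen and LPS-treated cells 26 and 42 (111 and 66.3 expected). Genes at that threshold in spleen and in cells labelled knockout went in opposite directions for 251 genes in naive cells and for 450 after LPS, and for 115 and 331 with the GC and length trend of each library removed.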

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

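All tests in this part were chosen after the results they bear on had been seen.

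Dixon's test picked out 4 of 44 spleen groups and measures, where chance flags about 1 in 20 groups, or 2.2 here. Ftl2-ps was lowest in wild-type replicate 5 at 54.8 CPM, with the others at 67.0 to 77.1 CPM. Abca8b was highest in wild-type replicate 7 at 5.11 CPM, with the others at 2.07 to 3.58 CPM. Masp2 was highest in wild-type replicate 10 at 18.4 CPM, with the others at 12.5 to 14.3 CPM. Haemoglobin genes took 23.7% of the counts in knockout replicate 4 and 4.16 to 13.3% in the other knockout spleens.

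The genotype effect of genes named in spleen differed between tissues in 29 of 40 tests, each of the spleen log2 fold change minus the dendritic cell value against both SEs. These genes were picked on their spleen values, the dendritic cell labels are in doubt, and read assignment seems to differ between the tissues. The trend with GC content also ran opposite ways. Its median rho was 0.148 in knockout and -0.128 in wild-type spleens. In LPS-treated cells it was -0.116 in those labelled knockout and 0.0317 in wild-type. The differences were not computed with that trend removed. Against naive cells the differences were 3.33 for Gpr82, 0.60 for Tgfb1, 0.74 for Slc16a3, 0.57 for Ftl1-ps1, 0.81 for Srebf2, 0.71 for Sf3b4, 0.47 for Actb and 0.48 for Arpc4. They were -1.32 for Rfx3, -0.67 for Fyco1, -0.99 for Zfc3h1, -0.73 for Masp2 and -0.50 for Fam214a. Against LPS-treated cells they were 3.83 for Gpr82, 0.78 for Tgfb1, 0.74 for Ftl2-ps, 0.82 for Slc16a3, 0.49 for Ftl1-ps1, 0.67 for Idi1, 1.01 for Srebf2, 0.56 for Sf3b4, 0.74 for Actb, 0.64 for Arpc4 and 2.35 for Pdgfra. They were -0.95 for Rfx3, -0.72 for Fyco1, -1.26 for Zfc3h1, -0.86 for Masp2 and -1.23 for Fam214a.

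Gpr34 had 104 to 120 counts in 3 of the 6 dendritic cell libraries labelled knockout, 4 in naive replicate 4 and 0 in replicate 2 of each treatment. A swap with a library labelled wild-type is argued against, since the lowest Gpr34 count among those was 65. A retained part of the gene read at a constant rate is argued against too, since the spleen ratio of 16.3% would give 14.3 and 35.6 counts in the libraries at 0. On an axis of 100 genotype genes chosen for each library from all others by their labels (0 for wild-type, 1 for knockout, a size set after other sizes were seen) the 3 libraries lay at 0.697 to 1.19, the other libraries labelled knockout at 0.375 to 0.683 and wild-type at -0.00219 to 0.359, which goes against a single wrong label, but that axis rests on the doubted labels themselves. On an axis chosen without the 3 they lay at 0.338 to 0.59, the undoubted libraries labelled knockout at 0.425 to 0.459 and wild-type at 0.0687 to 0.745, so it did not part the groups, a single wrong label or wild-type RNA stays open, and no biological explanation was tested.

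Naive replicate 3 labelled knockout stood apart from the other naive libraries. A wrong label for an LPS-treated library is argued against by its place at 31.4% of the way to those libraries on the leading principal component. Admixed RNA of LPS-treated cells is argued against by 46 strongly induced genes, which allowed a median share of 0.998%, while 17 maturation genes gave 32.1%. On log2 CPM the position of the maturation list was 43.4%, of the NF-kB list 16.1%, of the interferon list 7.95%, of the cell cycle list 71.6% and of the 46 induced genes 12.8%. The other naive libraries reached at most 3.02, 2.8, 5.87, 3.93 and 5.79% in turn. A hypothesis that these values leave open is maturation with little of the LPS response, found and tested on the same library.

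The 36 genes called in spleen stood beside a GC trend and 3 deviating knockout spleens. With each library's trend in GC content and transcript length removed 27 of them passed, and 23 of the 32 with a known GC content, with a median ratio of corrected to uncorrected log2 fold change of 0.775 in these, so the trend is argued against as the whole cause and may still enlarge part of the folds. Calls that ended had smaller folds, as for Zfp385a from 0.36 (SE 0.0742) to 0.07 (SE 0.116), Rfx3 from -0.79 (SE 0.151) to -0.44 (SE 0.119) and Abca8b from -0.85 (SE 0.168) to -0.57 (SE 0.201), or a smaller fold at a like SE, as for Slc16a3 from 0.58 (SE 0.118) to 0.50 (SE 0.119). Without knockout replicates 4, 6 and 9 31 of the 36 passed, which argues against those spleens as the cause of those calls. The loss of Gpr34 in the knockout stays open as an untested biological explanation.

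Other splits of the samples bear on each count of genes. In spleen 1 of 100 splits, the real one, gave as many as 36 genes and the highest other gave 0, so chance alone is unlikely to give that count. The splits ignored replicate numbers and cannot tell the genotype from a library trend that runs with it. For the interaction the real value was 0, which all 100 splits reach whatever the data, so their count decides nothing. The highest other split gave 15 genes, which may come from a structure of the samples that was not tested. In the other comparisons 10 splits are too few for a share under 0.05: the real value was 5743 in wild-type and 4875 in labelled knockout cells for LPS (1 of 10 splits each, highest other 0) and 0 for both genotype comparisons (10 of 10 splits, highest other 0).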

How the results depend on the processing

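The removal of the GC and length trend and the omission of doubted libraries, deviating spleens or haemoglobin genes were chosen after the data were seen. No named gene called in the main test changed sign under any alternative run. In spleen 405 of 580 values for 20 called genes stayed past the threshold and 175 did not, with LPS in wild-type cells 63 of 1236 did not, and in cells labelled knockout 66 of 1070. Counts are given as higher and lower, the cause of each change was not tested, and genes named here were chosen after their values were seen. For naive genotype (0 and 0) DESeq2 gave 45 and 32, voom 0 and 1, no filter 0 and 1 (Pls3), the trend removed 0 and 2 (Pls3, Rnmt), and single omissions 0 and 0 to 1: Pls3 without naive replicate 4 labelled knockout, Rnmt without LPS wild-type replicate 2. For LPS genotype (0 and 0) DESeq2 gave 224 and 148, and single omissions 0 to 2 and 0 to 1: Dst and Kpna4 without naive replicate 3, Pls3 without naive replicate 2, Chil6 and Ak1 without LPS replicates 2 and 4, all labelled knockout. Omitting the 3 doubted libraries left LPS replicate 2 alone in its group. Tcof1, Camk2a, Pdgfrb, Arsi and Slc6a7, of the run of neighbouring chromosome 18 genes in that library, were then higher and Depdc1b lower. LPS in wild-type cells (3064 and 2679) gave 1599 and 6128 without composition factors, 1642 lower (3795 in all against 5743) with the replicate block, and 2309 to 3050 and 2089 to 3068 over single omissions. In cells labelled knockout (2601 and 2274) the values were 1441 and 4986, and 1865 to 2936 and 1570 to 2672. The interaction (0 and 0) gave 11 and 11 with DESeq2 and 0 over single omissions. Without the doubted libraries LPS replicate 2 was alone in its group and assumed to vary like the other groups. Tcof1 and Pdgfrb, of its run of neighbouring genes, then had interaction values of 4.07 and 5.55, and Depdc1b of -8.89. Spleen (20 and 16) gave 461 and 439 with DESeq2 (20 and 16 shared), 383 and 407 with voom, 7 and 183 without composition factors (3.68% higher against 55.6%), 2 and 1 with the replicate block, 50 and 39 with the trend removed, and 179 and 118 without knockout replicates 4, 6 and 9. Single spleen omissions gave 4 to 524 and 4 to 527. Totals without knockout replicate 1, 2, 3, 4, 6, 7, 8 and 9 were 21, 23, 19, 22, 1051, 21, 8 and 23, and without wild-type replicate 1, 2, 3, 4, 5, 7, 9 and 10 were 23, 103, 22, 55, 15, 18, 23 and 17. Surrogate variables, no filter, RLE factors and no haemoglobin genes stayed within 1.5 times. Same-numbered dendritic cell libraries correlated at -0.0910 to 0.0747, none over the limit of 0.1 set for pairing. Same-numbered spleens correlated at -0.0782 to 0.290 (median 0.143 against -0.0205 for other pairs), with 5 of 9 over 0.1 against 16 of 81 other pairs. Of 18 spleens 7 correlated best with their own number, so a pairing of part of the spleens by number stays open. Every other count of called genes or lists stayed within 1.5 times under the block, while naive genotype genes at an unadjusted p under 0.05 were 713 against 1139. Lists called were 7 in naive cells, 0 with an estimated correlation or fry and 4 without the doubted libraries or naive replicate 3. For genotype after LPS they were 6 and for the interaction 4, and 0 in both with an estimated correlation or fry. Without naive replicate 3 the interaction lists passing were cholesterol, MHC class II, MAPK and macrophage markers. No count is given for these 2 comparisons without the doubted libraries, where LPS replicate 2 is alone in its group. For LPS they were 10 in wild-type cells (0 with an estimated correlation, 19 with fry) and 8 in cells labelled knockout (0 and 14). In spleen they were 12, and 0 with an estimated correlation, 1 with fry and 7 with the trend removed. At an unadjusted p under 0.05 the genotype effects shared 262 and 77 genes (naive and LPS), 14 and 37 (naive and spleen) and 26 and 42 (LPS and spleen), where 0 were shared at the adjusted threshold. With an estimated correlation, lists called were also 0 without the doubted libraries or with the trend removed, 2 in each LPS response and 0 in the other dendritic cell comparisons without naive replicate 3, and 1 in spleen without knockout replicates 4, 6 and 9. Without composition factors they were 2 for LPS in wild-type cells, 3 in cells labelled knockout and 0 elsewhere, a setting also chosen after the data were seen. Depth limits Gpr34 in dendritic cells, where 0 counts allow up to the floor of 3 counts.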

Other observations

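Of the tests in this part, those on chromosomes 18 and X and on runs of neighbouring genes were chosen after the values were seen, and the correlation of Gpr82 with Gpr34 was set before its result was seen.

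Pls3, Rnmt and Me2 were lower in each dendritic cell library labelled knockout than in every wild-type library of the same treatment, without passing over all genes. They are 3 examples chosen after their values were seen, and how many genes share this pattern was not counted. Groups did not overlap, in either direction, for 13.1% of the genes in naive cells and 17.5% after LPS, where chance gives 10%. Pls3, which bundles actin, was at 80.7 ± 9.07 CPM in LPS-treated wild-type and 31.1 ± 3.08 CPM in LPS-treated cells labelled knockout (SD, n = 3 each; log2 fold change -1.38, edgeR adjusted p = 0.152). Rnmt, which caps messenger RNA, went from 46.6 to 25.9 CPM in naive and from 47.0 to 29.0 CPM in LPS-treated cells, and Me2, the mitochondrial malic enzyme, from 34.1 to 19.1 CPM and from 20.7 to 11.9 CPM. In spleen Rnmt was at 25.6 to 35.3 CPM in knockout replicates 1, 2, 3, 4 and 6 and wild-type replicate 10, and at 47.8 to 65.0 CPM in the other spleens. Rnmt and Me2 lie on chromosome 18 and Pls3 on chromosome X. Of 67 genes at an unadjusted p under 0.01 in the same direction in both comparisons, 4 lay on chromosome 18 (1.47 expected, Fisher's exact p = 0.0592, adjusted 0.118) and 4 on X (2.48 expected, exact p = 0.315).

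A run of 6 neighbouring genes on chromosome 18 (60813755 to 61085061, GRCm38) stood over 10 times above every other library of its group in LPS-treated replicate 2 labelled knockout. Tcof1 was at 968.1 CPM of the plain library size, where the other dendritic cell libraries held 49.1 to 64.2 CPM, Camk2a at 794.8 CPM (at most 1.14 elsewhere) and Pdgfrb at 458.1 CPM (0.373 to 7.53 elsewhere). Slc6a7 at 141 CPM and Cdx1 at 37.6 CPM had 0 counts in all other dendritic cell libraries, and Arsi was at 28.3 CPM (at most 0.0862 elsewhere). The next longest such run in a dendritic cell library held 4 genes. In spleens the longest run held 10 genes, from Gm13775 to Mup20 on chromosome 4, in wild-type replicate 10. LPS-treated replicate 2 labelled knockout also had 0 counts of Gpr34 and of Gpr82. No cause was tested.

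Markers of sex differed between the tissues. Xist was at 193 ± 40.2 CPM of the plain library size in wild-type (SD, n = 10) and 118 ± 36.1 CPM in knockout spleens (SD, n = 9), and Ddx3y, Eif2s3y and Kdm5d had 0 counts in all spleens. Uty, also on chromosome Y, had 50 and 48 counts in wild-type replicates 7 and 9, 50 and 40 in knockout replicates 2 and 4 and 0 in the other spleens, while the dendritic cells, from male mice per the labels, had Ddx3y in each group. The Xist difference of -0.60 (SE 0.15) did not pass over all genes (edgeR adjusted p = 0.0760).

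Readthrough from the targeted locus is a hypothesis for the higher Gpr82 in every knockout spleen. It predicts that Gpr82 and the remaining Gpr34 reads rise together over the 9 knockout spleens. Pearson's r was 0.2 (exact permutation p = 0.596) and Spearman's rho 0.367 (exact permutation p = 0.336), and r was -0.135 without the 2 spleens farthest from the Gpr34 median, with 1 relation tested. The values leave the hypothesis open, since 9 spleens are few.

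At an unadjusted p under 0.05 in spleen and in naive cells labelled knockout were 302 genes, where independent lists would share 206.4. Of these 51 went the same way and 251 opposite ways. With the GC and length trend removed 49 and 115 of 164 did (142.5 expected). For LPS-treated cells the counts were 68 and 450 of 518 (349.4 expected), and 77 and 331 of 408 (279.7 expected) with the trend removed. The spleens held Xist and the dendritic cells came from male mice per the labels, so tissue and sex are not separated here.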
